A study of Mus musculus with 11 samples.

How the data were processed

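RNA was measured in 11 libraries of GFP-positive cells sorted from dissected, papain-treated V-SVZ tissue of mice of the CD1/Swiss strain at postnatal day 2. RNA was extracted with Trizol LS and the RNeasy Micro kit and libraries followed the Illumina TruSeq protocol, per the labels' protocols. The deposited values are raw read counts per Ensembl gene in 1 table of 39179 genes, with a column for each library and no further columns. TopHat2 2.0.13, featureCounts 1.4.6 and the builds mm10 and GRCm38 are named per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Without a stated strand setting, genes whose exons overlap on opposite strands cannot be told apart, and near-identical copies could share reads; named genes whose exons overlap another gene with a mean of at least 1 CPM are marked where they appear.

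Everything below was computed from those counts. Symbols and coordinates came from the GENCODE M21 annotation of GRCm38 and a table of gene names, which matched 37607 of the 39179 identifiers, holding 99.7% of the counts in every library. Groups came from the genotype in the labels: 6 control and 5 mutant libraries. Replicate libraries differed by more than sampling noise (chi-square per degree of freedom of at least 13.7 over genes with at least 10 counts in a pair), so each counted as 1 sample. Depth was 6833981 to 13073505 counts per library. Floors of 3 counts cover counting error only.

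Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM normalisation, the quasi-likelihood fit with robust estimation, and Benjamini-Hochberg adjustment over the 14104 genes kept, at a threshold of 0.05. All adjusted p-values of genes are from this test. CPM values in the text, means ± SD over 6 control and 5 mutant libraries included, are scaled by TMM factors unless said to be by library total. Mean levels of lists per library, and Zeb2, Xist and Ttr per library, are scaled by library totals. The standard error of a log2 fold change was derived from it and the F statistic. The 31 gene lists were written before the data were examined; 730 of their 735 entries were in the table. The 26 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. No list call held with an estimated correlation. With fry, the striatal, mitosis, replication, interneuron, migration and Zeb2-linked lists passed, as did the epithelial junction list (adjusted p = 0.0114). Library measures, and Zeb2 on the log2 CPM scale, were compared with exact two-sided permutation tests over all 462 splits, using Python 3.11.15 and scipy 1.17.1.

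Named genes followed a rule fixed before the data were examined. They are Zeb2; the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those past the threshold, with a mean log2 CPM of at least 1 and every mutant library on the same side of the control mean; and from each list up to 4 members with the smallest adjusted p, or where none passed up to 2 with the highest mean level. Some genes that the rule or a count would name are not reported here. The test was checked on simulated counts with 200 changed genes among 14104: it recovered 56% of the genes changed 2-fold and 89% of those changed 4-fold, and 5 unchanged genes were called, 3.33% of all calls. In a simulation of gene lists 10 of 10 lists raised 1.5-fold were called and 0 of 20 unchanged lists. The simulated genes varied independently of one another, whereas the estimated correlation within the striatal list, for example, was 0.506. These list rates therefore do not carry over to lists of correlated genes.

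Alternatives fixed in advance were RLE, upper quartile and no composition scaling, no filter and a stricter filter (CPM of at least 1 in 5 libraries), DESeq2 1.42.0, limma-voom with and without library weights, a fit without robust estimation, thresholds of 0.01 and 0.1, leaving out each library, a replicate block, the level of 4 Y-linked genes as a covariate, and 1 surrogate variable from sva 3.50.0. Chosen after seeing the data were female libraries only, leaving out control 6 and mutant 5, leaving out the gene Gm42418, removing GC content or exon length trends per library, and an estimated correlation for lists called only under another setting. Gm42418 alone held 6.25% to 12.2% of the counts of a library, with the largest share in mutant 5.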

Results

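The series measured mRNA levels in cells of the ventricular-subventricular zone (V-SVZ), the germinal layer along the lateral ventricles, of mouse brains at postnatal day 2. Cells carrying GFP, which marks the lineage of cells that expressed Cre under the Gsh2 promoter, were sorted by flow cytometry from dissected tissue. The labels give 6 control libraries, from animals with 1 floxed and 1 wild-type Zeb2 allele, and 5 libraries labelled mutant, with 1 floxed and 1 null allele. Total counts ranged from 6833981 to 13073505 per library and between 16836 and 18649 genes had at least 1 count. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries. The titles name Gsh2-Cre for both groups, so the floxed allele would be deleted in the sorted cells of the controls too. The comparison therefore sets cells expected to keep 1 allele of Zeb2, a zinc finger transcription factor gene, against cells expected to keep none. The null allele of the mutants is not limited to this lineage.

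The gene-level count of Zeb2 (ENSMUSG00000026872, chromosome 2, positions 44983632 to 45117395, minus strand, GRCm38) was not lower in the libraries labelled mutant. Zeb2 stood at 239 ± 48.9 CPM (counts scaled by library totals; SD, n = 6) in the controls and at 302 ± 71.5 CPM (SD, n = 5) in the libraries labelled mutant, a difference within the spread between libraries (log2 fold change 0.35, SE 0.165, adjusted p = 0.294; exact two-sided permutation p = 0.156, where the smallest possible value is 0.00433). The control libraries 1 to 6 held 1650, 3277, 2184, 2553, 2527 and 1669 Zeb2 counts, and the mutant libraries 1 to 5 held 4754, 2574, 3086, 4508 and 2573. A gene-level count includes reads from exons outside the deleted part, and exons of the opposite-strand gene Zeb2os overlap Zeb2, so the count does not check the genotype. The directions below therefore rest on the labels.

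The groups also differed in sex as read from the counts. Control libraries 1, 2, 3 and 6 held 763, 2716, 1780 and 810 counts of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y. Control libraries 4 and 5 and all 5 libraries labelled mutant held 0, with Xist, the noncoding RNA of the inactive X chromosome, at 274 CPM or more in each. In the 4 controls with Y-linked counts Xist held at most 10 counts. Of the 14104 genes tested, 597 lay on the X chromosome and 21 of these changed, against 623 changed in all (odds ratio 0.782, two-sided Fisher's exact p = 0.309). With only female libraries (2 controls against 5 mutants, a comparison chosen after seeing the data) 218 genes changed, 200 of them among the 623, and all 622 of the 623 that could be tested there kept their sign. Their median absolute log2 fold change was 1.12 there against 1.15 in all libraries, and their median standard error 0.275 against 0.212. The 623 were called on libraries that include the female ones, so the kept signs and similar sizes are not an independent check. With the level of the Y-linked genes as a covariate 189 genes changed.

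**Figure D1:**
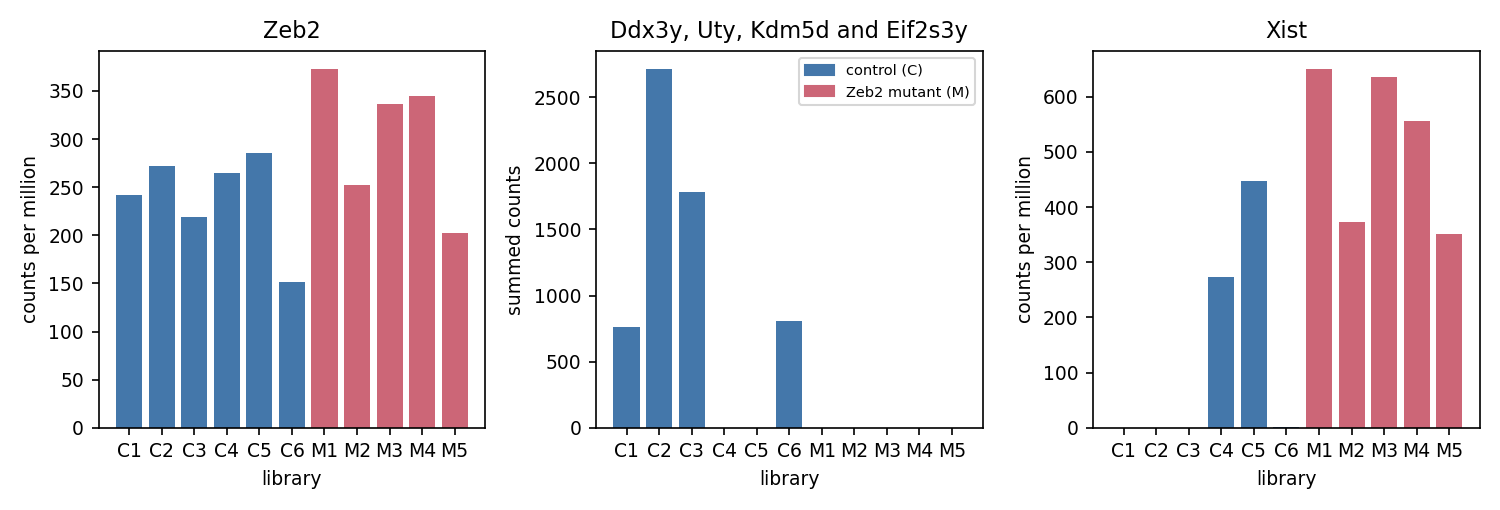
Bars give, for each control (C) and Zeb2 mutant (M) library, the Zeb2 level in CPM, the summed counts of 4 Y-linked genes and the Xist level in CPM. Zeb2 overlapped between the groups, and Y-linked counts appeared in control libraries 1, 2, 3 and 6.

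In the libraries labelled mutant 6 of 18 genes of cortical and medial ganglionic eminence (MGE) interneurons rose, Sst, Npy, Sox6 and Lhx6 among them, and 3 fell (list adjusted p = 0.187 with an estimated correlation). Of 21 genes of striatal projection neurons 9 fell, including Rxrg, Foxp1, Adora2a and Bcl11b, and 2 rose (list adjusted p = 0.272 with an estimated correlation). Sst stood at 93.6 ± 28.1 CPM (SD, n = 6) in the controls and 661 ± 108 CPM (SD, n = 5) in the mutants, and Rxrg at 221 ± 87.7 and 44.0 ± 15.3 CPM. The single genes Nrp1 and Dcc, which encode guidance receptors, rose. Of 38 genes of mitosis 4 fell, and of 35 of DNA replication 2 fell (list adjusted p = 0.255 and 0.187 with an estimated correlation), and none of either list passed among female libraries. In all, 623 of 14104 genes changed at an adjusted p of 0.05, with 378 higher and 245 lower. At least a 2-fold change was seen for 246 of the higher genes and 118 of the lower ones. All libraries of one group lay apart from all of the other for 693 genes, or 4.91% of those tested, where chance gives 0.433%.

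Among genes with a mean log2 CPM of at least 1, the largest increases included Foxi3, a forkhead transcription factor gene on chromosome 6 (70956531 to 70961066). It had no counts in the 6 controls and 12.7 ± 5.89 CPM in the mutants, which makes it at least 39.8-fold higher against a floor of 3 counts per library. Fam20a, which encodes a secretory pathway pseudokinase, rose from 1.85 ± 0.857 to 57.5 ± 9.16 CPM (log2 fold change 4.96, SE 0.313, adjusted p = 2.62e-07). Calb2, which encodes the calcium-binding protein calretinin, rose from 20.3 ± 13.03 to 292 ± 65.6 CPM (log2 fold change 3.87, SE 0.359, adjusted p = 1.69e-05). Trhde, encoding an enzyme that degrades thyrotropin-releasing hormone, rose by 4.03 on the log2 scale, and Col6a3 and Fli1, a collagen chain and an ETS transcription factor, by 4.81 and 4.70. Tmem215, Dcdc5, Ankrd34b and Exph5 completed this group, with log2 fold changes of 5.02, 4.47, 4.46 and 4.03. Among female libraries Tmem215, Ankrd34b and Exph5 were not past the threshold (log2 fold changes 4.96, 3.596 and 3.44, adjusted p = 0.0539, 0.19 and 0.148), nor with the Y-linked covariate were these 3, Dcdc5 and Fli1 (3.50 to 5.16, adjusted p from 0.0593 to 0.279). Exons of Dcdc5 overlap those of Dnajc24 on the opposite strand, so its counts are uncertain.

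Among the largest decreases at that level, Cav1, which encodes caveolin-1, fell from 6.84 ± 1.38 to 0.694 ± 0.791 CPM (log2 fold change -3.26, SE 0.731, adjusted p = 0.0181). Rxrg, a retinoid X receptor gene, fell from 221 ± 87.7 to 44.0 ± 15.3 CPM (log2 fold change -2.33, SE 0.302, adjusted p = 0.00035). Dclk3, Arhgdib and Sfrp4, the last a secreted Wnt antagonist gene, had log2 fold changes of -2.32, -2.31 and -2.43. Sln, Rbm24, Caln1 and Spon2 had log2 fold changes of -3.39, -2.66, -2.64 and -2.42. Each of these 4 calls was lost in at least 6 of the 11 fits that left out 1 library, in which Sln ranged from -4.90 to -2.93, Rbm24 from -3.35 to -2.35, Caln1 from -2.90 to -2.09 and Spon2 from -2.63 to -2.10. Of the genes named here, Sfrp4, Rxrg and Dclk3 stayed past the threshold among female libraries, and the others had log2 fold changes from -3.47 to -2.21 there.

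**Figure D2:**
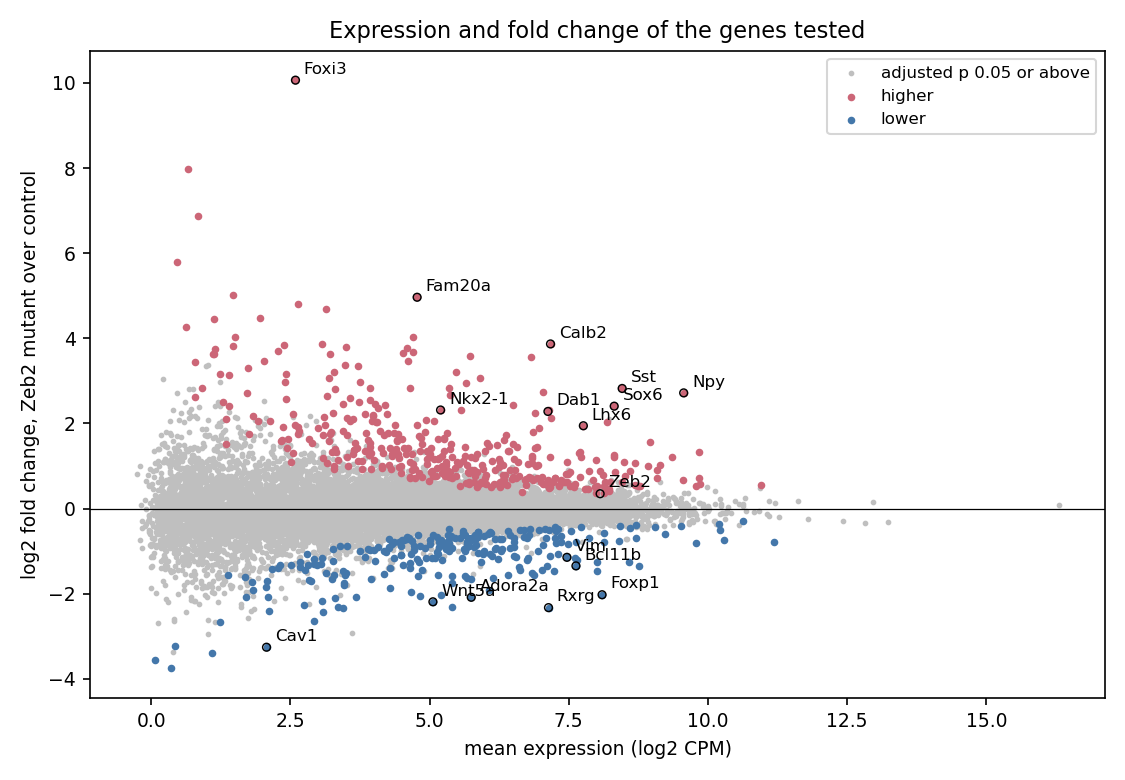
Each point is 1 of the 14104 genes tested, placed by mean expression (log2 CPM) and log2 fold change of Zeb2 mutant over control, with the 378 higher and 245 lower genes in colour and named genes labelled. The fitted value of Foxi3 depends on the prior count, since its controls are at 0.

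Of 18 tested genes on the interneuron list, 6 rose, 3 fell and 9 did not pass, and 7 and 4 passed when adjusted over the list alone. Sox6 (chromosome 7, 115470872 to 116038796), a transcription factor gene of MGE-derived interneurons, rose from 108 ± 10.2 to 571 ± 111 CPM (log2 fold change 2.41, SE 0.125, adjusted p = 1.02e-07). Sst and Npy, which encode the neuropeptides somatostatin and neuropeptide Y, rose by 2.82 and 2.72 on the log2 scale, with Npy reaching 1408 ± 235 CPM. Lhx6 and Nkx2-1, transcription factor genes that specify the MGE lineage, rose by 1.95 and 2.32, and Nxph1 by 1.10. Crabp1 and Cxcr4 fell, with log2 fold changes of -1.60 and -1.73. Crabp1, Cxcr4 and Nxph1 were named after their values were seen. The list as a whole was called higher by camera (adjusted p = 2.98e-08), but not with an estimated correlation (adjusted p = 0.187), and its median log2 fold change was 0.10 against a mean of 0.40. The list's mean level, in log2(CPM + 1), was 4.20 to 4.94 in the controls and 4.83 to 5.35 in the mutants, with mutant 5 lowest among the mutants and within the range of the controls. Among female libraries 5 members were past the threshold higher and 1 lower.

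On the striatal projection neuron list 9 of 21 tested genes fell, 2 rose and 10 did not pass, with 14 and 2 when adjusted over the list alone. Adora2a, an adenosine receptor gene of the indirect pathway, fell from 82.1 ± 22.7 to 19.4 ± 3.73 CPM (log2 fold change -2.09, SE 0.212, adjusted p = 3.88e-05). Foxp1 and Bcl11b, transcription factor genes of these neurons, fell from 417 ± 201 to 102 ± 20.1 CPM and from 273 ± 86.3 to 107 ± 13.8 CPM. Exons of Foxp1 overlap Gm20696 on the same strand. Drd2, the D2 dopamine receptor gene, had a log2 fold change of -1.55, whereas Drd1, the D1 receptor gene, rose from 9.03 ± 3.67 to 21.6 ± 4.95 CPM and Pcp4 rose by 1.45 on the log2 scale. Drd1, Drd2 and Pcp4 were named after their values were seen. The list was called lower (median log2 fold change -1.35, adjusted p = 2.85e-09), though not with an estimated correlation (adjusted p = 0.272). The mean level of the whole list, in log2(CPM + 1), was 4.37 in control 1 and 4.89 to 5.91 in the other controls, against 3.69 to 4.65 in the mutants, so control 1 lay among the mutants. Among female libraries 5 members were past the threshold lower and 0 higher.

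**Figure D3:**
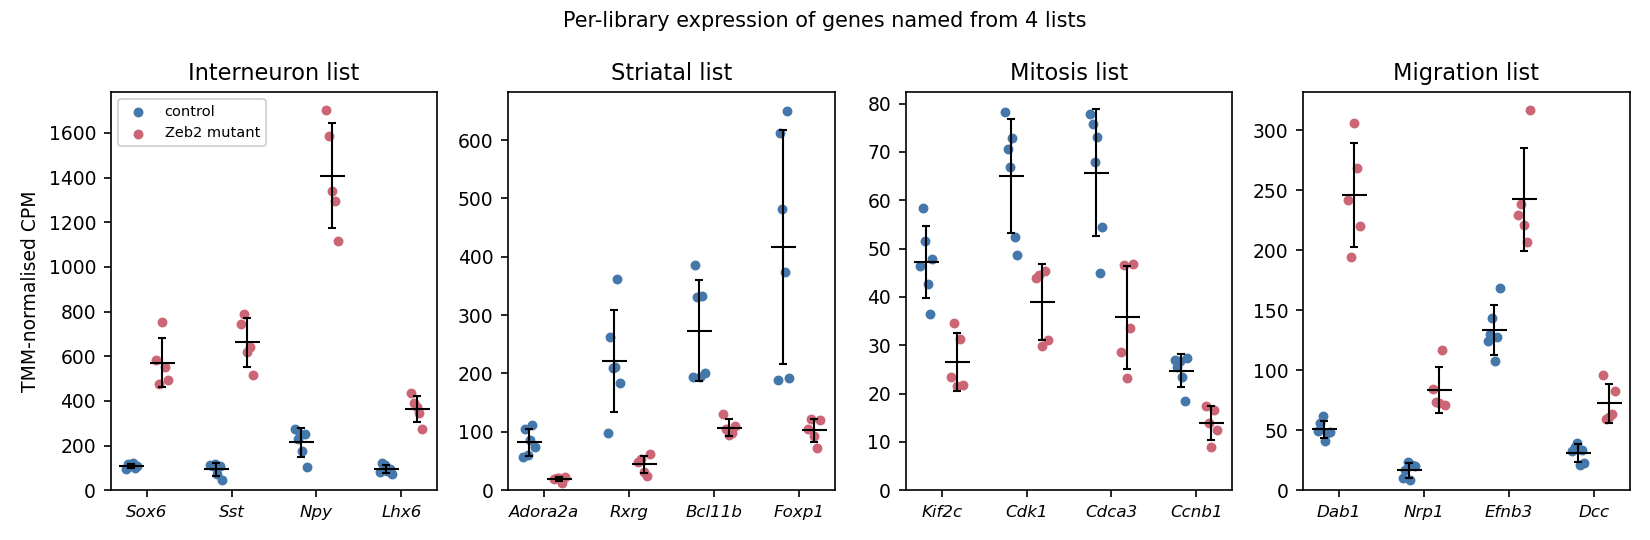
Points give each library's TMM-normalised CPM for 4 genes from each of 4 lists, and bars give the mean and SD of 6 control and 5 Zeb2 mutant libraries. For Sox6, Sst, Npy and Lhx6 every mutant library lay above every control, and for Adora2a, Rxrg, Bcl11b and Foxp1 every mutant library lay below every control.

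Of 38 genes of neuroblast migration and axon guidance 10 rose, 3 fell and 25 did not pass, with 13 and 5 when adjusted over the list alone. Dab1, an adaptor of the reelin pathway, rose from 50.6 ± 7.19 to 246 ± 43.3 CPM (log2 fold change 2.28, SE 0.139, adjusted p = 2.62e-07). Nrp1, a semaphorin receptor gene, rose by 2.32, Dcc, a netrin receptor gene, by 1.23, and Efnb3, an ephrin gene, by 0.86 on the log2 scale. The 3 that fell were Vldlr, Efnb2 and Cxcr4, named after their values were seen, and Vldlr, a reelin receptor gene, had a log2 fold change of -0.92. Camera called the list higher (median log2 fold change 0.21, adjusted p = 1.93e-05), and this was lost with an estimated correlation (adjusted p = 0.187). In female libraries 6 members were past the threshold higher and 1 lower.

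On the young neuron list no common shift passed the test (33 tested, 2 higher, 3 lower, 28 not past; 6 and 5 adjusted over the list alone; camera adjusted p = 0.97). Gad2, a GABA-synthesising enzyme gene, rose from 334 ± 75.6 to 670 ± 76.0 CPM, and Rbfox3, which encodes the neuronal nuclear antigen NeuN, rose by 1.23 on the log2 scale. Tiam2, Dpysl3 and Cd24a, the last named after its values were seen, fell, with log2 fold changes of -0.82, -0.29 and -0.36. The calls of Tiam2 and Dpysl3 were lost in 7 and 9 of the 11 fits without 1 library (ranges -0.91 to -0.64 and -0.32 to -0.26), and exons of Tiam2 overlap Tfb1m on the opposite strand. Dpysl3 also lost its call among female libraries (-0.275, adjusted p = 0.356), and Gad2 and Rbfox3 lost theirs with the Y-linked covariate (0.73 and 1.31, adjusted p = 0.0718 and 0.0767). On the olfactory bulb interneuron list 3 of 20 genes rose, 1 fell and 16 did not pass (4 and 3 adjusted over the list alone; camera adjusted p = 0.319 upward, with a median of -0.08 and a mean of 0.30). Calb2, Pax6 and Neurod1 rose, with Pax6 going from 132 ± 23.4 to 306 ± 50.2 CPM, while Prox1, whose exons overlap Prox1os, had a log2 fold change of -0.56 and lost its call without mutant 1 (-0.52, adjusted p = 0.0562). Among female libraries Neurod1 and Prox1 were not past the threshold, at log2 fold changes of 2.075 and -0.59 against 2.07 and -0.56 in all libraries (adjusted p = 0.136 and 0.159). On the pallial and excitatory neuron list Neurod1 alone passed among 14 genes, also when adjusted over the list alone (camera adjusted p = 0.243, and 0.0499 without control 1, where adjusted p = 0.579 with an estimated correlation).

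No mitosis gene rose, 4 of 38 fell and 34 did not pass, but 13 fell when adjusted over the list alone, and the list's median log2 fold change was -0.54 (camera adjusted p = 9.43e-09; adjusted p = 0.255 with an estimated correlation). Kif2c, a mitotic kinesin gene, fell from 47.3 ± 7.49 to 26.5 ± 6.04 CPM (log2 fold change -0.83, SE 0.177, adjusted p = 0.0128). Cdk1, Cdca3 and Ccnb1 had log2 fold changes of -0.73, -0.88 and -0.83, and each lost its call in at least 5 of the 11 fits without 1 library, in which Cdk1 stayed between -0.81 and -0.66, Cdca3 between -1.001 and -0.76 and Ccnb1 between -0.93 and -0.71. Of 35 DNA replication genes, Mcm3 and Rrm1 fell, with log2 fold changes of -0.47 and -0.42, and 33 did not pass, with 2 lower when adjusted over the list alone (median -0.30, camera adjusted p = 1.93e-05; adjusted p = 0.187 with an estimated correlation). Both genes lost their calls in at least 6 of the 11 fits without 1 library (Mcm3 from -0.53 to -0.41, Rrm1 from -0.51 to -0.37). Among female libraries no gene of either list was past the threshold, and the medians were -0.56 for mitosis and -0.35 for replication.

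Progenitor and glial lists gave less stable calls. Of 25 neural stem cell and radial glia genes, Vim and Ednrb fell, Hopx rose and 22 did not pass, the same numbers as when adjusted over the list alone; Vim, the vimentin gene, went from 236 ± 43.0 to 106 ± 20.5 CPM. Ednrb lost its call in 7 of the fits without 1 library (-0.93 to -0.68), and was at -0.53 among female libraries (adjusted p = 0.399). Hopx was at 2.645 among female libraries against 2.17 in all (adjusted p = 0.0668), and its call held with the Y-linked covariate (adjusted p = 0.0477). That list was called lower (median -0.37, adjusted p = 0.00589, and adjusted p = 0.627 with an estimated correlation). The call was lost without mutant 2 (adjusted p = 0.0806, median -0.235) and among female libraries (adjusted p = 0.573, median -0.10). The transit-amplifying progenitor list was not called (adjusted p = 0.2, and 0.0374 without control 5, where adjusted p = 0.451 with an estimated correlation). Mfng, a Notch glycosyltransferase gene, fell from 145 ± 41.4 to 62.6 ± 7.503 CPM and the other 18 genes did not pass, with 1 higher and 2 lower when adjusted over the list alone.

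On the oligodendrocyte precursor list Gpr17 fell and 19 of 20 genes did not pass, although 11 fell when adjusted over the list alone (median -0.54, camera adjusted p = 5.54e-05; adjusted p = 0.465 with an estimated correlation). Control 6 had the highest mean level of this list, 6.23 in log2(CPM + 1) against 5.17 to 5.67 in the other controls, and Gpr17, whose exons overlap Lims2, stood there at 402 CPM. The call of Gpr17 was lost without control 3, mutant 1, mutant 2, mutant 3 or mutant 4, and its log2 fold change of -1.44 ranged from -1.63 to -1.05 over the fits without 1 library. Among female libraries the list was not called (adjusted p = 0.454, median -0.25). The astrocyte list was called lower with 1 of 19 genes past the threshold, Slc4a4 (3 lower when adjusted over the list alone, median -0.30, adjusted p = 0.0353, and adjusted p = 0.627 with an estimated correlation). Slc4a4, with a log2 fold change of -1.13, lost its call in 6 of the fits without 1 library, over which it ranged from -1.29 to -0.996. The call of the astrocyte list was lost without control 2, control 3, control 6, mutant 1 or mutant 2 (adjusted p from 0.109 to 0.184, medians from -0.27 to -0.222). Among female libraries the median of that list was 0.15. On the myelinating oligodendrocyte list Nfasc and Mbp rose and 8 of 10 did not pass, with 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.97 upward, with a median of -0.09 and a mean of -0.16). Nfasc lost its call without mutant 1 or mutant 3 (0.63 and 0.57), and Mbp without mutant 3 or mutant 4 (0.55 and 0.58). Among female libraries Gpr17, Slc4a4, Nfasc and Mbp were not past the threshold (log2 fold changes -0.75, -0.92, 0.84 and 0.645, adjusted p from 0.12 to 0.336).

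The list of genes linked to Zeb2 in other tissues held 5 tested members. Nkx2-1 and Unc5b, a netrin receptor gene, rose by 2.32 and 2.06 on the log2 scale, and Sfrp1, Fgf9 and Smad7 did not pass, with values of 0.45, 1.398 and -1.24. Sfrp1, Fgf9 and Smad7 were named after their values were seen. The call of Unc5b was lost without control 4, mutant 4 or mutant 5 (2.01, 1.90 and 1.94) and with the Y-linked covariate (2.36, adjusted p = 0.218). With the adjustment over the list alone 4 were higher. The list was called higher (adjusted p = 0.000278; adjusted p = 0.0761 with an estimated correlation), with a median of 1.52 among female libraries. On the list of Zeb and Snail family genes none of 4 tested genes passed, and Zeb1, whose exons overlap Gm10125, stood at 148 ± 38.6 and 154 ± 29.5 CPM.

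**Figure D4:**
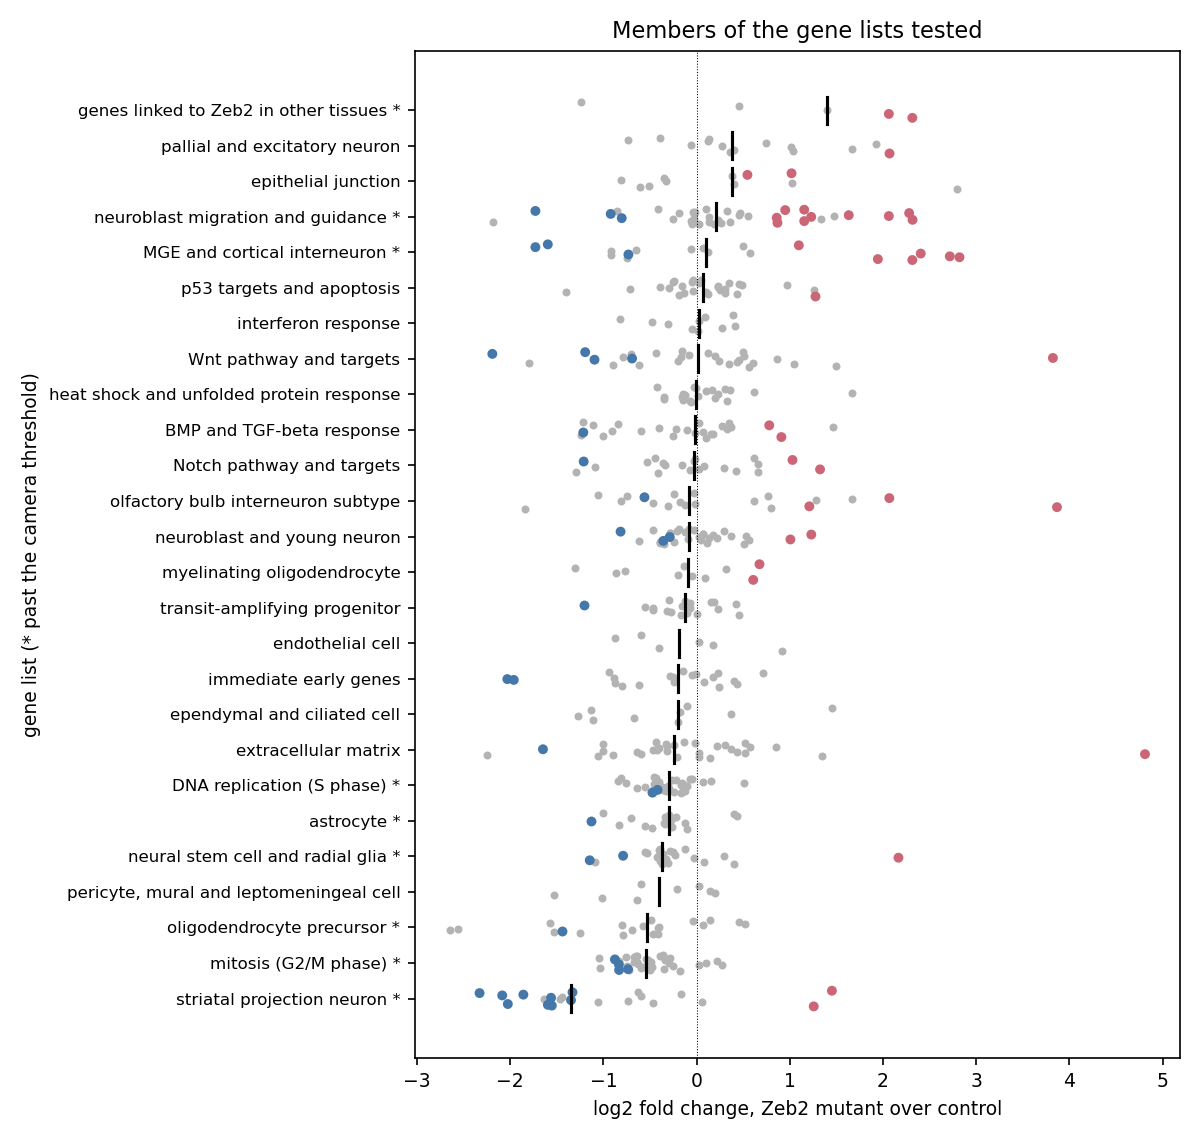
Each point is a tested member of 1 of 26 gene lists, at its log2 fold change of Zeb2 mutant over control, coloured where it passed the threshold, and a black line marks the list median. The striatal list has the lowest median, -1.35, and the list of genes linked to Zeb2 elsewhere the highest, 1.398, and asterisks mark the lists called by camera.

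Among signalling lists, single genes changed and no list was called. In the Wnt list 1 of 28 genes rose, 4 fell and 23 did not pass (camera adjusted p = 0.567 downward, with a median of 0.02 and a mean of 0.01), with 3 and 4 when adjusted over the list alone. Wnt5a, a noncanonical Wnt ligand gene, fell from 51.6 ± 20.2 to 11.2 ± 4.26 CPM, Ccnd1, Sfrp2 and Dkk3, the last named after its values were seen, had log2 fold changes of -1.20, -1.10 and -0.69, and Wif1, a Wnt inhibitor gene, rose by 3.82 from a control level of 0.337 ± 0.389 CPM. Exons of Wnt5a and Ccnd1 overlap genes on the opposite strand. In the Notch list Dner and Dll4, both Notch ligand genes, rose by 1.03 and 1.33, Mfng fell and 18 of 21 did not pass (4 and 2 adjusted over the list alone; camera adjusted p = 0.97 upward, with a median of -0.03). In the BMP and TGF-beta list Tgfbr1 and Id2 rose, Smad3 fell with a log2 fold change of -1.22, and 22 of 25 did not pass (2 and 2 adjusted over the list alone; camera adjusted p = 0.82). Smad3 lost its call without mutant 3 (-1.12), Tgfbr1 without mutant 1, mutant 3 or mutant 4 (0.74, 0.72 and 0.75), and Id2 in 8 of the fits without 1 library (0.76 to 1.09). Cdkn1a, a cell cycle inhibitor gene, rose from 14.5 ± 4.67 to 34.9 ± 6.23 CPM, the only p53 target to pass among 28 (1 and 1 adjusted over the list alone; camera adjusted p = 0.567). Wnt5a, Dner and Mfng stayed past the threshold among female libraries and with the Y-linked covariate. Ccnd1, Sfrp2, Wif1, Dll4, Smad3, Tgfbr1, Id2 and Cdkn1a were past it in neither (adjusted p from 0.109 to 0.337 among female libraries and from 0.0718 to 0.421 with the covariate). Their log2 fold changes among female libraries were -1.13, -0.96, 3.57, 1.49, -1.16, 0.51, 0.93 and 0.998, against -1.20, -1.10, 3.82, 1.33, -1.22, 0.78, 0.91 and 1.27 in all libraries.

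Of the remaining lists, the epithelial junction list had Cdh2 and Cdh4, both cadherin genes, higher among 11 (3 adjusted over the list alone; camera adjusted p = 0.243), and Cdh4 lost its call in 6 of the fits without 1 library (0.89 to 1.21). In the extracellular matrix list Col6a3 rose, Tnr, the tenascin-R gene, fell with a log2 fold change of -1.65, and 31 of 33 did not pass (1 and 3 adjusted over the list alone; camera adjusted p = 0.256). Cdh2 and Tnr were not past the threshold among female libraries (0.40 and -1.495, adjusted p = 0.23 and 0.137). Among 20 immediate early genes Arc and Npas4, which neuronal activity induces, fell (2 higher and 3 lower when adjusted over the list alone; camera adjusted p = 0.44), but their calls were lost in 4 and 5 of the fits without 1 library (Arc from -2.14 to -1.44, Npas4 from -2.22 to -1.47). Among female libraries, where controls 4 and 5 are the 2 controls, both passed with log2 fold changes of -2.94 and -3.01 (adjusted p = 0.000215 and 0.00122), as with the Y-linked covariate (-2.84 and -2.95, adjusted p = 0.000645 and 0.00182). Controls 4 and 5 held 55.0 and 96.4 CPM of Arc, the other controls 12.6 to 27.4 CPM and the mutants 7.65 to 11.2 CPM. That list was called lower among female libraries (median -0.40, adjusted p = 5.59e-06) and with the Y-linked covariate (adjusted p = 2.59e-05), but in neither with an estimated correlation (adjusted p = 0.337 and 0.195). No heat shock or unfolded protein gene passed among 21 (camera adjusted p = 0.97 upward, with a median of -0.01 and a mean of 0.10), and no interferon response gene among 10 (camera adjusted p = 0.872 downward, with a median of 0.02 and a mean of -0.04).

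The ependymal, endothelial and pericyte, mural and leptomeningeal lists were not called. No member passed among 9 ependymal (camera adjusted p = 0.524), 6 endothelial (camera adjusted p = 0.97) or 8 pericyte, mural and leptomeningeal genes (camera adjusted p = 0.302; 1 lower when adjusted over the list alone). No member passed among 3 microglial and 3 choroid plexus genes, 2 lists too short for camera. Bpgm, which encodes bisphosphoglycerate mutase, was the only one of 3 genes on the red blood cell list to pass and rose by 0.61 on the log2 scale, a call lost with the Y-linked covariate (0.65, adjusted p = 0.0739). Of the sex-linked genes only Xist and Tsix were tested, whose exons overlap and which did not pass (log2 fold changes 2.11 and 1.79). In exact permutation tests of 10 planned measures, which covered total counts, genes detected, the share of the 50 most abundant genes, 6 marker lists and the Y-linked genes, the smallest adjusted p was 0.487. Mutant 5 held 2456 counts of the choroid plexus gene Ttr, or 193 CPM by library total, where the other libraries held 0 to 8 counts.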

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

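The tests of sex, cell makeup and labels in this part were chosen after the results were seen; the counts over other splits of the libraries were set before.

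A library far from the rest of its group was found in 18 of the 245 group-wise checks made on library measures, list levels and named genes, where chance gives about 1 in 20, or 12.2. Control 6 had the fewest genes detected, 16836 against 17707 to 18211 in the other controls, and the lowest mean level of the young neuron list, 8.03 in log2(CPM + 1) against 8.27 to 8.40. It also held the most Mbp and Tekt1 among the controls, 67.2 and 15.6 CPM. Mutant 5 stood apart in Ttr with 193 CPM by library total, and among the mutants in Cspg4 with 45.5 CPM, Rrm1 with 358 CPM and Sln with 1.16 CPM. Control 1 had 0 CPM of Trhde against 3.33 to 4.34 in the other controls, and 8.33 CPM of Sln. Control 3 was highest in Rbm24 with 6.81 CPM, Sfrp2 with 41.05 CPM and Dll4 with 8.19 CPM. The other single values were Dcdc5 in control 4 at 1.15 CPM, Caln1 in control 5 at 31.3 CPM, Arhgdib in control 2 at 26.95 CPM, Hopx in mutant 4 at 10.35 CPM and Foxj1 in mutant 2 at 5.62 CPM.

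Chance is an unlikely source of the counts of changed genes, though splits of the libraries do not separate genotype from sex. Of 100 splits into groups of 6 and 5, drawn from 462 and with the real one included, 1 gave as many changed genes as the real 623. The highest of the others gave 1. The same held for higher genes (1 split of 100; 378 against at most 1) and lower genes (1 split of 100; 245 against at most 1). Every other split drawn placed libraries labelled mutant and control in both groups. A real difference between the labelled groups would then widen the spread within groups and lower the gene counts. The size of those counts therefore does not show what chance alone gives. For the 9 gene lists called by camera chance is not excluded, since 14 of the 100 splits called as many lists and the highest of the others called 13.

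The first pattern is the rise of 6 interneuron genes, Nkx2-1, Lhx6, Sst, Npy, Sox6 and Nxph1, in libraries labelled mutant. Sex as the whole cause is argued against, since 5 of the 6 stayed past the threshold among female libraries alone, where their median log2 fold change was 2.53 against 2.36 in all libraries. The 6 were picked on libraries that include the female ones, so this is not an independent check. A larger share of cells of this lineage in the sort could raise these 6 together (median 2.36), and that cannot be told apart from a change within cells, because the counts are sums over sorted cells. The 3 list members that fell, Cxcr4 and Crabp1 among them, had a median log2 fold change of -1.33 among female libraries against -1.60 in all, but they were picked on these libraries and 1 passed there, so they leave this open. A change in gene expression after loss of Zeb2 stays open as a hypothesis.

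The second pattern is the fall of 9 striatal genes. Sex as the whole cause is again argued against, with 5 of the 9 past the threshold among female libraries and a median log2 fold change of -2.06 there. The 9 too were picked on libraries that include the female ones. The controls there were 4 and 5, with mean list levels of 4.89 and 5.91 in log2(CPM + 1), the latter the highest of all libraries. Control 1, the lowest control at 4.37, was left out, so the size of the female median depends on which controls remain. Fewer striatal projection neurons in the sort could lower the 9 genes together (median -1.60), and the design leaves that open. The 2 members that rose, Drd1 and Pcp4, had log2 fold changes of 1.33 and 1.08 among female libraries (median 1.21, adjusted p = 0.302 and 0.106), but they were picked on these libraries and leave it open too. A change within cells after loss of Zeb2 is a hypothesis that stays open here too.

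The third pattern is a Zeb2 count that was not lower in the libraries labelled mutant. A single mislabelled library, or a pair swapped between groups, is argued against, because all 11 libraries lay with their own group on the first principal component, which held 24% of the variance. Reads from exons that the deletion leaves could keep the gene-level count up: 0 of 5 mutant libraries lay below the lowest control, but the counts are not split by exon and the deleted exon is not named in the labels, so this cannot be told apart from a retained allele. An exchange of the labels of all libraries was not tested.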

How the results depend on the processing

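The count of 623 changed genes, 378 higher and 245 lower, stayed within 1.5 times under other scalings (619 to 639), filters, limma-voom, the fit without robust estimation and 3 of the settings chosen after seeing the data, namely those without Gm42418, with GC content or with exon length trends removed (622, 777 and 630), and it was 629 without control 6 and mutant 5, also chosen afterwards. All of the 623 genes that could be tested kept their sign in every alternative, and the median log2 fold change of all genes stayed between -0.044 and 0.012. Every alternative reused libraries on which the genes were called, so the kept signs are not an independent check. DESeq2 called 1108 genes (613 higher, 495 lower), voom with library weights 375 lower genes, and 1 surrogate variable 955 genes, 593 of them higher; the cause was not tested. With the Y-linked level as a covariate 189 genes changed (123 higher, 66 lower), with 1 degree of freedom fewer. That level averaged 3.317 in log2(CPM + 1) over the controls and 0 over the mutants, so it is partly confounded with genotype. Among female libraries, chosen after seeing the data, 218 genes changed (150 higher, 68 lower), with 2 controls. An adjusted p of 0.01 left 286 genes (204 higher, 82 lower) and one of 0.1 gave 976, with 421 lower. Leaving out 1 library at a time gave 418 to 656 changed, 269 to 405 higher and 149 to 251 lower genes; the lower count moved by over 1.5 times without control 4 (162) and without mutant 1 (156), mutant 3 (149) or mutant 4 (160). Of 70 named genes past the threshold, 45 kept their call in all 11 of these fits and 35 among female libraries, and 25 in those fits, among female libraries and with the covariate. The 9 gene lists called became 7 to 10 in the other fits and 0 with an estimated correlation. The astrocyte list turned upward among female libraries (0.148) and with the covariate (0.137), in neither case past the threshold. Same-numbered libraries did not deviate together (correlations -0.038, -0.073, 0.021, 0.019 and -0.137, with control 3 alone best matched by its own number), so the counts showed no pairing by number. The labels do not say what the numbers mark, so shared litters or days stay possible. Control 6 and mutant 5 lay together on the second principal component (16.1% of the variance), at -54.5 and -57.5. The next lowest library there, mutant 2, was at -16.7. Control 6 was also the best match of mutant 5 among the controls. Whether control 6 and mutant 5 share a batch was not tested. With the replicate block, which left out control 6 and set mutant 5 with control 5, 421 genes changed (278 higher, 143 lower). Simulated 2-fold changes were recovered in 24% of genes at or below their median level of 26.8 CPM and in 88% above it, and depth was not varied on its own.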

Other observations

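The gene families and the imprinted genes below were chosen, and their tests set, after reading through the called genes, so these tests are partly circular; the test around Zeb2 was set before its result was seen.

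Imprinted genes, which are expressed from 1 parental allele, were frequent among the genes that rose. Of 49 tested genes from a list of 66 imprinted genes, 10 rose and 0 fell (odds ratio 9.53, 95% confidence interval 4.21 to 19.63, two-sided Fisher's exact p = 5.49e-07), although the median of all 49 was 0.02. Dlk1, which encodes a noncanonical Notch ligand, rose from 1.20 ± 0.372 to 9.59 ± 2.51 CPM, and Plagl1, a zinc finger transcription factor gene, from 14.1 ± 2.96 to 48.7 ± 17.0 CPM. Ndn and Peg3 rose by 0.58 and 0.89 on the log2 scale, and Zdbf2, Blcap, Nnat, Mest, Nap1l5 and Usp29 made up the rest, with exons of Mest overlapping Copg2. Nnat lies within the span of Blcap, and Usp29 starts next to the end of Peg3. Fisher's exact test treats such neighbours as independent, so its p-value and interval may be overstated. All called genes here and below kept their sign under the other scalings. Camera gave p = 0.000733 for the whole list and p = 0.0136 with an estimated correlation. A hypothesis is that imprinted genes shift as a group in these cells. Sex as the whole cause is argued against, since the median log2 fold change of the 10 was 0.967 among female libraries against 1.06 in all, with all 10 of the same sign and over 2 standard errors. Of the 10, 2 stayed past the threshold there, where the median standard error was 0.245 against 0.172 with all libraries. The 10 were picked on libraries that include the female ones, so this is not an independent check.

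Of 107 ion channel subunit genes 12 rose and 2 fell (odds ratio 3.31, adjusted p = 0.000424), including Trpc5 and Kcnv1 among those that rose and Cacna1h among those that fell. Camera gave p = 0.00146 for this family and p = 0.166 with an estimated correlation. Of 23 glutamate receptor genes 7 rose, among them Grik1 and Gria4, and Grm5 and Grik3 fell (odds ratio 14.09, adjusted p = 1.42e-06; camera p = 0.000955, and p = 0.118 with an estimated correlation). Of 49 cadherins and protocadherins 8 rose and 1, Pcdh9, fell (odds ratio 4.92, adjusted p = 0.000424; camera p = 0.00369, and p = 0.152 with an estimated correlation). Of 14 synaptotagmins Syt1, Syt6, Syt13 and Syt14 rose (odds ratio 8.70, adjusted p = 0.00331; camera p = 4.93e-07, and p = 0.0194 with an estimated correlation). Of 77 cytosolic ribosomal protein genes 2 fell, Rplp0 and Rpl4 (odds ratio 0.58, 95% confidence interval 0.07 to 2.16, adjusted p = 0.777), an interval that leaves both a higher and a lower frequency open. Their median log2 fold change was -0.35, and 71 of the 77 lay below 0 under each of the 4 scalings (medians from -0.371 to -0.345). Camera gave p = 1.73e-08 for that shift, which was lost with an estimated correlation (p = 0.126). The adjusted p-values are from two-sided Fisher's exact tests over the 5 families, the camera p-values are not adjusted, and genes of a family are not independent replicates.

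Around Zeb2, 7 of 74 tested genes within 10 Mb changed, namely Gsn, Lhx6, Nek6, Lypd6b, Lypd6, Rnd3 and Tnfaip6 (odds ratio 2.27, two-sided Fisher's exact p = 0.0445). Both groups carry a floxed allele, and only the libraries labelled mutant carry the null allele. Alleles of another strain carried along with the null allele could contribute to calls there, and Lhx6 is one of the interneuron genes that rose. The labels name 1 strain for all libraries, so this was not tested further.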
